A study of Escherichia coli with 6 samples.

How the data were processed

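Total RNA of E. coli K-12 MG1655 and of its hsdM mutant was isolated with a Norgen column kit, per the labels' protocols, and sequenced as 6 libraries, 3 per group. Reads were trimmed with Trimmomatic 0.36, per the submitters' processing notes. The aligner, the counting program, the genome build, the annotation, the library kit and whether counting used the strand are not given in the sources used here.

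The authors deposited raw read counts per gene and library, whole numbers named as raw counts per the file headers. They also deposited normalized counts, a signal that equals the raw count times 1 factor per library, from 13.1 to 39.3, to within 0.0888% for values from at least 1000 reads. These factors put the upper quartile of each library between 98822 and 99951. The RPKM and Expression columns hold 1 rounded score per group, deposited by the authors with no value per library, and how the Expression score was made is not given in the sources used here. The p-values and q-values of the authors' deposited table compare the groups, with no test named per the file headers. Only the raw counts were tested. Normalized counts, scores and deposited p-values were used to describe the files.

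The count table has 4357 entries, of which 39 are predicted RNAs with no gene symbol of their own, 1 of them described as antisense to rnpB. These were left out of library sizes and tests and held 0.294% ± 0.0529 (SD, n = 3) of the counts in the parent and 0.580% ± 0.152 (SD, n = 3) in the mutant. Of the 4318 named genes, 4174 passed edgeR's default low-count filter. Symbols and positions are those of the deposited table. The build is not given in the sources used here, and a RefSeq gene table of assembly ASM584v2 was used for names and gene types, with 4314 IDs matched.

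Counts were compared in R 4.3.3 with edgeR 4.0.16, using TMM factors, the quasi-likelihood test (two-sided) with group as the only term and Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. Fold changes are edgeR's log2 values of mutant over parent, with the standard error taken from the size of the effect and its test statistic. CPM values use TMM-scaled library sizes. Gene lists, 36 of them with 879 entries, were written from textbook knowledge before the data were examined, as were the design, the rule for named genes and the first set of alternative settings. Of these entries, 855 were matched by symbol, 11 through RefSeq synonyms or symbols and 13 not at all. Lists with at least 5 tested members were compared with other genes by camera of limma 3.58.1 (two-sided, preset correlation of 0.01, adjusted over 36 lists), leaving hsdM out. Camera was repeated with an estimated correlation per list, and fry tested whether a list's genes moved on balance one way or in either direction. With an estimated correlation 0 of the 9 calls held, and fry adjusted over 36 lists called 1 list for a shared direction, the NADH dehydrogenase and cytochrome oxidases.

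Genes are named by a rule. It takes 7 restriction genes, 8 topology genes, up to 12 genes per direction among those past the threshold that do not overlap between groups and reach a mean of 10 CPM in a group, and up to 4 members with the smallest p of each list with a member past the threshold. For lists past camera with no such member, it takes the member with the smallest p. The remaining called genes, further members of the 9 lists past camera, fruB, rbsD, yjiA, yjiX and tnaA were named after their values were seen.

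The moving median of log2 fold change was taken around the circular chromosome in the order of the deposited positions, over 50 genes, with 1000 random gene orders. Coding length was computed from translation start and stop for 4031 tested genes. Lists were compared with 10000 random lists in which each gene was replaced by 1 of the 100 genes nearest in coding length. Relative levels by coding length use log2(CPM + 0.1).

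The libraries are deep. Totals ran from 58160827 to 86055142 counts and the median count per named gene from 538 to 1875. Differences between libraries of a group were far above counting noise: for any pair of libraries the chi-square per gene, over genes with at least 20 counts in the pair, was 2602 or more, so that no library was counted as a duplicate of another. The value is a mean over genes of counts scaled by library totals, without TMM factors and with rnpB and ssrA kept in. The uneven share of these RNAs enters it, and it need not be the value of a typical gene. How much of this spread arose in the cultures and how much in library preparation was not tested. Correlations of log2 CPM between libraries, across genes, ran from 0.791 to 0.983.

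The tests were checked on simulated counts for the comparison of mutant and parent, drawn with the real means, library sizes and dispersions. In 5 simulations of 4153 genes on average, 200 of them changed, edgeR recovered 36.4% of changes of 4-fold, 94.0% of 16-fold and 99.7% of 64-fold, with 4.98% false among its calls. DESeq2 1.42.0 recovered 67.2% at 4-fold with 19.6% false among its calls. A shift of 4-fold in 1 list was called in 5 of 5 simulations with 0 other lists called. Each gene was drawn independently, with the same mean profile in all libraries apart from the changed genes. The simulations thus lack the correlation between genes and the structure of the samples found in the real counts, and their rates need not carry over.

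Alternatives were RLE factors, DESeq2, limma-voom, no low-count filter, a filter at a mean of 50 counts, rRNA and tRNA genes left out, the replicate number as a block, each library left out, and windows of 20 and 100 genes. Chosen after seeing the data were upper-quartile factors, library quality weights in voom, the rnpB and ssrA share as a covariate, parent library 1 and mutant library 3 both left out, rnpB and ssrA left out before library sizes, and random orders of blocks of 10 genes. Python 3.11.15 with numpy 2.4.6 was used for positions and lengths. A comparison of genes with and without EcoKI recognition sites was not run, since no genome sequence was used here.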

Results

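RNA was sequenced from cultures of Escherichia coli K-12 strain MG1655 and from cultures of an isogenic hsdM mutant, with 3 libraries per group. The hsdM gene encodes the methylating subunit of EcoKI, a type I restriction–modification enzyme whose other subunits, HsdR and HsdS, cut DNA and recognise the target sequence. Per the series design, the 3 libraries of each group came from separate cultures harvested in mid exponential phase in LB, a rich medium. The title of the series ties such systems to gene expression and DNA topology, so the comparison asks which transcripts differ when the methylating subunit is lost. Total counts were 71115747, 86055142 and 75893250 in parent libraries 1 to 3 and 74323060, 58160827 and 64931210 in mutant libraries 1 to 3.

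A pair of stable RNAs took up a large and uneven part of these counts. The catalytic RNA of RNase P, rnpB, and the transfer-messenger RNA, ssrA, together held 57.9% ± 11.9 (SD, n = 3) of the counts on named genes in the parent and 22.4% ± 13.9 (SD, n = 3) in the mutant. The share was 49.4%, 71.5% and 52.9% in parent libraries 1 to 3 and 38.5%, 14.8% and 14.0% in mutant libraries 1 to 3, with no overlap. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. Protein-coding genes held 37.8% ± 11.9 (SD, n = 3) of the counts in the parent and 74.8% ± 16.4 (SD, n = 3) in the mutant. Ribosomal RNA genes held at most 0.0350% of the counts in any library. Of the variance between libraries in log2 CPM, 60.1% lay on the first principal component, on which parent library 1 (3.43) and mutant library 1 (3.64) sat side by side, parent libraries 2 and 3 lay at -53.1 and -55.0, and mutant libraries 2 and 3 lay at 27.4 and 73.6.

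**Figure D1:**
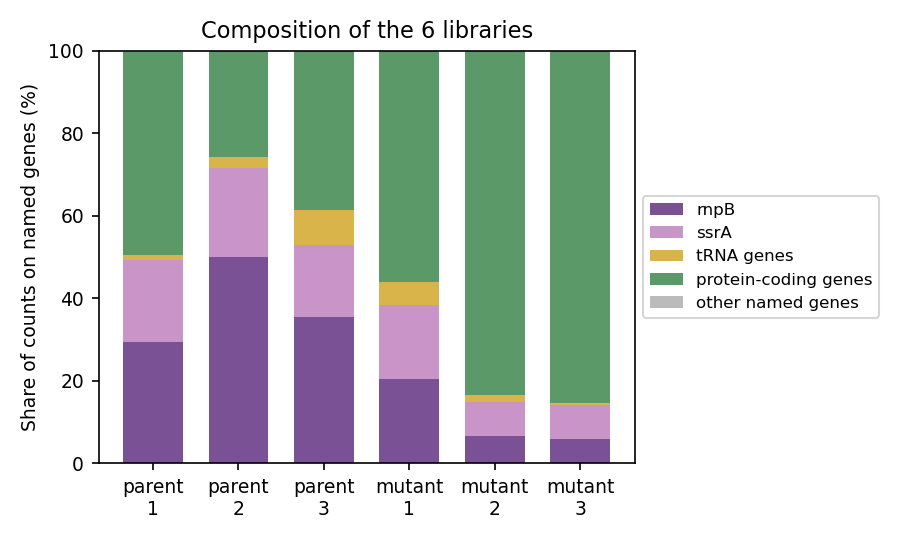
Share of the counts on named genes, in percent, that fell on rnpB, ssrA, tRNA genes, protein-coding genes and other named genes, one stacked bar per library. The 3 parent bars carry 49.4% to 71.5% on rnpB and ssrA together and the 3 mutant bars 14.0% to 38.5%.

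The targeted gene was nearly silent in each mutant library. In the parent libraries, hsdM (b4349) had 2653, 1343 and 2371 counts, and in the mutant libraries 9, 10 and 16. Its level was 38.3 ± 3.88 CPM (SD, n = 3) in the parent and 0.121 ± 0.0208 CPM (SD, n = 3) in the mutant. The log2 fold change of mutant over parent was -8.28 (SE 0.42), with an adjusted p of 0.000453 in the edgeR quasi-likelihood test. Each library thus carried the hsdM level that its label called for.

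Around hsdM, the genes of the same chromosomal segment did not move as a block. The deposited table places hsdM on the minus strand at positions 4581459 to 4583048 of the single chromosome, with hsdR upstream at 4583249 to 4586761 and hsdS downstream at 4580068 to 4581462, overlapping hsdM by a few bases. Further downstream on the same strand lie symE, which encodes a toxin-like protein, and mcrB and mcrC, which encode a restriction enzyme that cuts methylated DNA. In the main edgeR fit, none of these neighbours passed the threshold over all genes. The values nearest to it belonged to mcrB (b4346), at 5.83, 4.79 and 6.85 CPM in the parent and 20.8, 33.5 and 29.1 CPM in the mutant libraries (log2 fold change 2.25, SE 0.35, adjusted p = 0.0717 in edgeR). For mcrC the log2 fold change was 1.73 (SE 0.49), for hsdR 1.37 (SE 0.60), for hsdS -0.56 (SE 0.33), for symE 0.18 (SE 0.48) and for mrr, another gene of methylated-DNA restriction on the plus strand, -0.02 (SE 0.49). The signs for symE and mrr turned under some alternatives, and that of hsdR turned when the rnpB and ssrA share was a covariate. Of the 18 alternative fits, mcrB passed the threshold over all genes in 4, mcrC in 2 and hsdR in 1. As a list fixed in advance, the 12 tested neighbours of the hsd locus had a median log2 fold change of 0.78, with 4 members higher when adjusted over the list alone (mcrB, mcrC, yjiA and yjiX) and 0 over all genes. The competitive list test gave an adjusted p of 0.0394 in limma camera with the preset correlation, and p = 0.202 (adjusted p = 0.696) with an estimated correlation. The call was kept in 11 of 18 alternative fits and lost without parent library 2, parent library 3 or mutant library 1 (adjusted p = 0.0675, 0.0983 and 0.0762 in camera). It was also lost in DESeq2, in limma-voom, with no low-count filter and with the share covariate (0.0561, 0.0800, 0.0584 and 0.256). The list median ran from -0.19 with the rnpB and ssrA share as a covariate to 1.14 with library quality weights, and was 0.19 with no low-count filter. The groups overlapped in the median over the list of log2 CPM minus each gene's mean. Parent library 1 (0.29) lay above mutant libraries 1 and 3 (0.17 and 0.23).

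**Figure D2:**
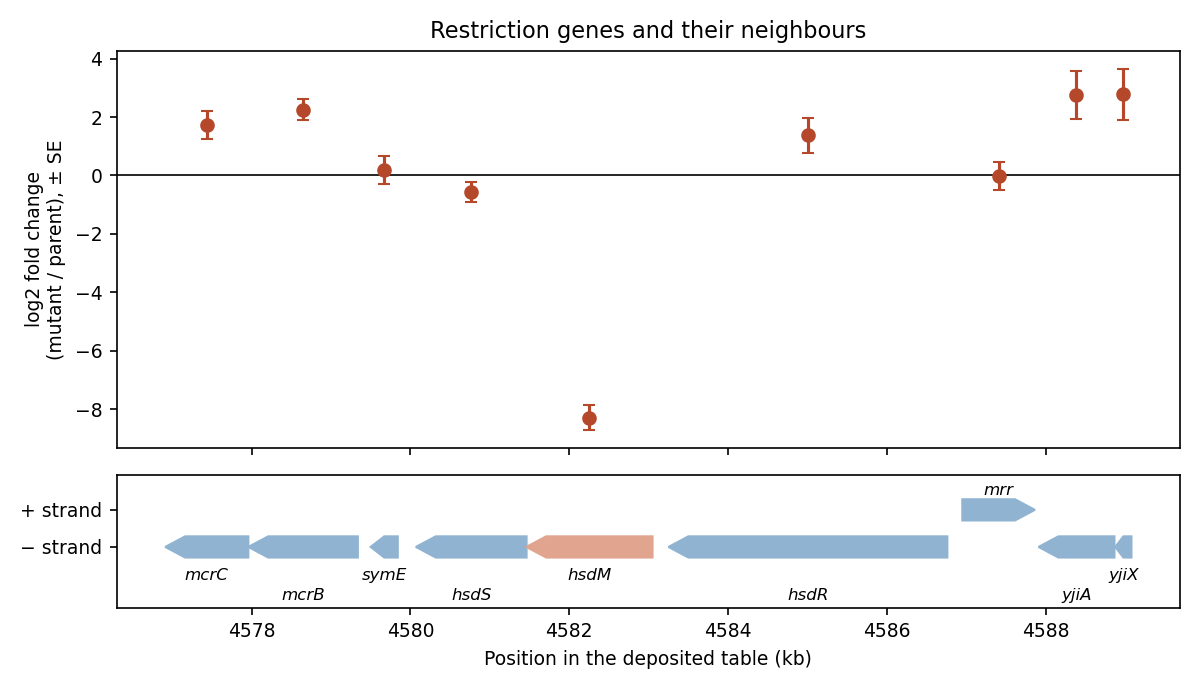
Log2 fold change of mutant over parent with its standard error (top, 6 libraries) and the position and strand of each coding region in kb (bottom) for mcrC, mcrB, symE, hsdS, hsdM, hsdR, mrr, yjiA and yjiX. In the main edgeR fit only hsdM, at -8.28, passed the threshold over all genes, and mcrB stood at 2.25. The sign of the mrr and symE values, both close to 0, turned with the scaling or the libraries used, and that of hsdR with a covariate.

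Across the transcriptome, 10 of 4174 tested genes differed at an adjusted p under 0.05 in edgeR, 3 higher and 7 lower in the mutant, and all 10 had a log2 fold change of at least 1 in size. The 3 that rose were fimC (b4316) and fimI (b4315) of type 1 fimbriae, the surface fibres that bind mannose, and nuoM (b2277), a membrane subunit of the proton-pumping NADH dehydrogenase. With fimC the level went from 1.07 ± 0.192 CPM (SD, n = 3) to 14.0 ± 4.88 CPM (SD, n = 3), a log2 fold change of 3.70 (SE 0.43, adjusted p = 0.0418), and fimI rose by 3.48 (SE 0.43). The nuoM transcript went from 57.7 ± 7.57 CPM (SD, n = 3) to 487 ± 143 CPM (SD, n = 3), a log2 fold change of 3.07 (SE 0.41, adjusted p = 0.0455). Besides hsdM, the genes that fell were the cold shock genes cspI (b1552) and cspG (b0990), the stress-inducible envelope gene bhsA (b1112), ycfJ (b1110), the nitrogen regulatory gene glnK (b0450) and ynfN (b1551), a prophage gene. Their log2 fold changes were -4.62 (SE 0.42) for cspI, -3.81 (SE 0.48) for cspG, -3.39 (SE 0.41) for bhsA, -3.27 (SE 0.36) for ycfJ and -3.46 (SE 0.45) for glnK. For ynfN, counts of 16, 12 and 13 in the parent stood against 0, 0 and 1 in the mutant libraries, and no fold is given. Most of the genes that fell were low in absolute terms, with cspI at 1.69 CPM and glnK at 1.51 CPM in the parent.

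Many more genes were separated between the groups than passed the correction. At an unadjusted p under 0.05 there were 949 genes, 416 higher and 533 lower. If no gene differed between the groups and the libraries had no other structure, 208.7 would be expected. Of the tested genes, 29.7% had no overlap between the groups, where chance gives 10%. The biological coefficient of variation was 0.527. The count of called genes depended on the libraries used: without parent library 1 it was 60, without parent library 3 it was 78, and without parent library 2 or any single mutant library it was 1, which was hsdM in each case. The other called genes kept their sign in every alternative fit that tested them, with fimC from 2.54 to 3.94, nuoM from 2.32 to 3.24 and ycfJ from -3.41 to -2.82. DESeq2 on the same 4174 genes called 552, of which 246 were higher and 306 lower; with the rnpB and ssrA share as a covariate edgeR called 0 (78 at an unadjusted p under 0.05).

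Of the 36 gene lists, that of the TCA cycle had the highest median log2 fold change in the edgeR fit with TMM factors. All 16 tested TCA cycle genes had positive log2 fold changes, with a median of 3.18, and 14 of them did not overlap between the groups. The median was 0.54 with the rnpB and ssrA share as a covariate, 2.09 without mutant library 3 and 4.11 without parent library 1. Over all genes 0 passed, and adjusted over the list alone 11 were higher. The values were 4.55 (SE 0.73) for sucD and 4.14 (SE 0.81) for sucC, the subunits of succinyl-CoA synthetase, 3.91 (SE 0.63) for sucB of 2-oxoglutarate dehydrogenase and 3.31 (SE 0.78) for icd, isocitrate dehydrogenase. In camera the adjusted p was 8.93e-12, and p = 0.103 (adjusted p = 0.696) with an estimated correlation. In the list of NADH dehydrogenase and cytochrome oxidases, 1 of 23 genes, nuoM, rose over all genes and 13 were higher when adjusted over the list alone. The median log2 fold change was 1.66 (1.01 to 2.04 over the 18 alternative fits), and nuoK (3.06, SE 0.43), nuoJ (2.46, SE 0.36) and nuoI (2.72, SE 0.45) of the same operon lay beside nuoM. Its camera adjusted p was 4.32e-11, and p = 0.0146 (adjusted p = 0.525) with an estimated correlation.

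Genes for the use of secondary carbon sources went both ways. Of 83 tested, 71 had positive log2 fold changes and the median was 1.68, with 0.84 without mutant library 3 and 2.97 without parent library 1. Adjusted over the list alone, 11 were higher and 6 lower, and over all genes 0 passed. Per library, the median over the list of log2 CPM minus each gene's mean was 0.42, -1.54 and -1.83 in parent libraries 1 to 3. In mutant libraries 1 to 3 it was 0.38, 0.73 and 2.12, so the groups overlapped. Sorbitol-6-phosphate dehydrogenase, srlD, had 18.1 ± 18.6 CPM (SD, n = 3) in the parent and 1039 ± 772 CPM (SD, n = 3) in the mutant, a log2 fold change of 5.84 (SE 1.06). The galactose genes galK and galM had values of 3.44 (SE 0.66) and 2.44 (SE 0.51). In the other direction, fruA and fruB of fructose uptake had -3.72 (SE 0.80) and -4.58 (SE 0.997), and rbsD of ribose use had -3.74 (SE 0.95). The camera adjusted p was 7.82e-12, and p = 0.256 (adjusted p = 0.696) with an estimated correlation; with the rnpB and ssrA share as a covariate the list median turned to -0.30.

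The list of type 1 fimbriae and curli genes lay higher by its median, with 12 of 15 log2 fold changes positive and 3 negative. Over all genes 2 passed the threshold, and 6 were higher when adjusted over the list alone. The median log2 fold change was 0.81, with 0.17 under the share covariate, 1.36 with the stricter filter, and 1.24 and 1.21 without parent library 1 or 3. Next to fimC and fimI the values of fimG and fimF were 2.34 (SE 0.34) and 2.001 (SE 0.34). These are all genes of type 1 fimbriae, and the curli genes were not tested on their own. By camera, the adjusted p of this list was 6.57e-07, and p = 0.04995 (adjusted p = 0.696) with an estimated correlation.

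Lists that lay lower in the mutant held cold shock, capsule, iron and motility genes. Of 12 cold shock genes, 2 fell over all genes and 6 were lower when adjusted over the list alone, and the list median was -1.73 (-2.27 without mutant library 1 to -0.48 with the share covariate). The RNA chaperone gene cspA had 1669 ± 1184 CPM (SD, n = 3) in the parent and 158 ± 117 CPM (SD, n = 3) in the mutant (log2 fold change -3.40, SE 0.95), and cspB had -3.25 (SE 0.87). These csp genes resemble each other in sequence, and how reads shared between them were counted is not given in the sources used here. The camera adjusted p was 8.58e-07, and p = 0.0877 (adjusted p = 0.696) with an estimated correlation. Of 21 genes of colanic acid, a capsular polysaccharide, 12 were lower when adjusted over the list alone and 0 over all genes, with a median of -1.62 (-2.08 without parent library 3 to -0.89 with the share covariate) and values of -2.52 (SE 0.59) for wzc, -1.88 (SE 0.43) for wcaA and -1.48 (SE 0.35) for wcaL. For this list camera gave an adjusted p of 1.66e-07, and p = 0.165 (adjusted p = 0.696) with an estimated correlation. Parent library 3 lay near the mutant in the list's median of log2 CPM minus each gene's mean. The values were 1.10, 1.64 and -0.58 in parent libraries 1 to 3 and -0.67, -0.83 and -0.80 in mutant libraries 1 to 3. Of the 21 genes, 8 did not overlap, against 29.7% of all tested genes. Levels were low, with wcaA at 0.77 CPM in the parent and 0.21 CPM in the mutant.

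Among 36 iron uptake genes, 34 had negative log2 fold changes, with a median of -0.86. The enterobactin receptor gene fepA (-2.01, SE 0.37) was the 1 member lower when adjusted over the list alone, 0 passed over all genes, and the enterobactin synthesis genes entC and entE had -1.91 (SE 0.44) and -1.995 (SE 0.52). Camera gave the iron genes an adjusted p of 9.91e-06, and p = 0.166 (adjusted p = 0.696) with an estimated correlation. For 49 flagella and chemotaxis genes the median was -0.49, 0 passed over all genes or adjusted over the list alone, and the values nearest the threshold were those of the receptor gene tar (-1.81, SE 0.50) and the flagellin gene fliC (-1.32, SE 0.40). The camera adjusted p was 0.0394, and p = 0.316 (adjusted p = 0.696) with an estimated correlation. This call too was kept in 11 of 18 alternative fits, and it was lost without parent library 1, parent library 3, mutant library 1 or mutant library 2 (adjusted p = 0.0835, 0.0983, 0.0687 and 0.148 in camera), in DESeq2 (0.0561) and with the stricter filter (0.0579), among others. The rnpB and ssrA share, 49.4% or more in the parent and 38.5% or less in the mutant, differed between the same groups as these 9 lists.

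**Figure D3:**
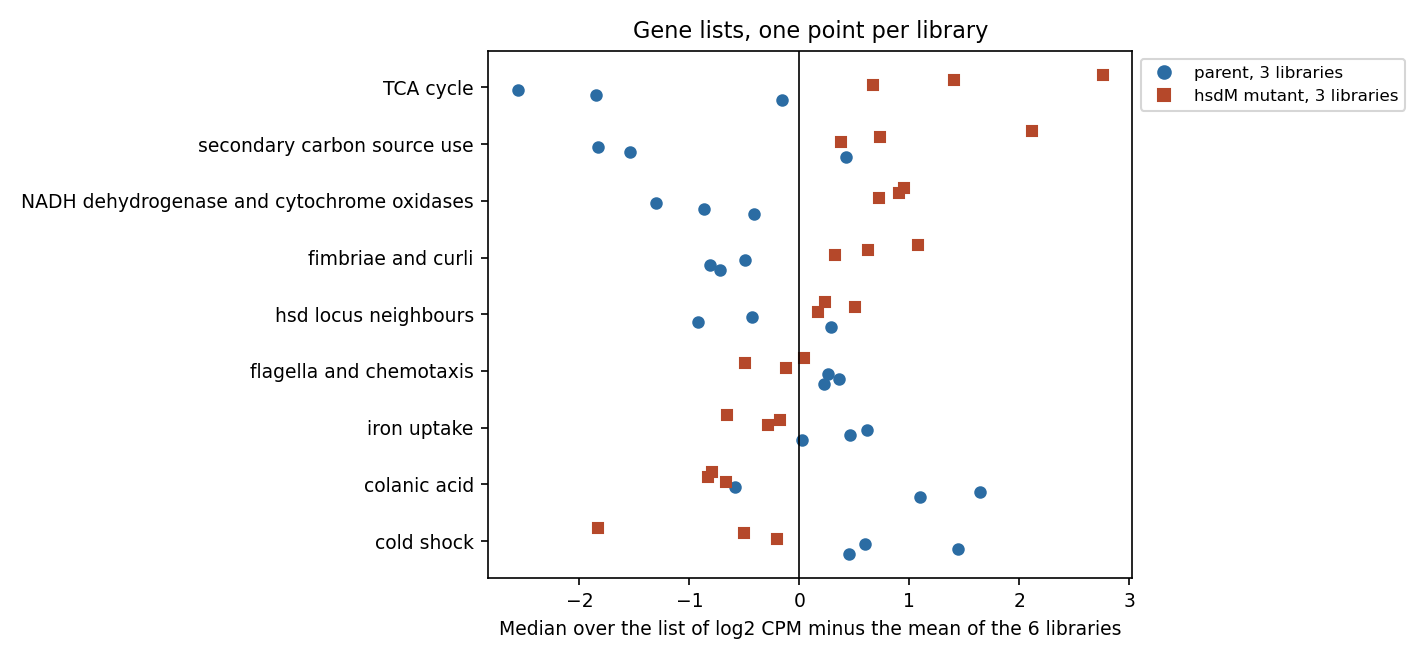
Median over each list's members of log2 CPM minus the gene's mean over the 6 libraries, one point per library, for the 9 lists past the camera threshold with the preset correlation. The TCA cycle list ran from -2.56 to -0.16 in the parent (circles) and from 0.67 to 2.76 in the mutant (squares), and parent library 1 lay nearest the mutant in it.

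Genes that set DNA topology, the subject of the series title, showed no call in the main edgeR fit. Of 18 alternative fits, hupA passed the threshold over all genes in 2. The DNA gyrase genes gyrA and gyrB had log2 fold changes of 0.09 (SE 0.43) and -0.40 (SE 0.42), and the topoisomerase genes topA and topB had -0.05 (SE 0.46) and 0.45 (SE 0.34). Among nucleoid proteins, the values were -0.57 (SE 0.98) for fis, -0.08 (SE 0.42) for hns, -1.90 (SE 0.51, adjusted p = 0.136 in edgeR) for hupA and -0.71 (SE 0.38) for hupB. Both HU genes, hupA and hupB, were lower in 3 of 3 mutant libraries than in any parent library, while topB was higher in 3 of 3. For topB the margin was small, with 137.8 CPM in parent library 2 and 138.2 CPM in mutant library 1. Of all tested genes, 29.7% had no overlap between the groups. Both HU genes have coding regions under 300 nt, a class with a median log2 fold change of -0.57. The signs for gyrA, gyrB, topA, fis and hns turned under some alternatives. Of 24 genes in the list of DNA topology and nucleoid proteins, 0 passed over all genes or adjusted over the list alone, the median was -0.21 and the camera adjusted p was 0.757. The 17 tested genes with supercoiling-responsive promoters had a median of -0.05 and a camera adjusted p of 0.757, with 2 higher and 1 lower when adjusted over the list alone and 0 over all genes. The median of this list turned with the fit, from -0.36 to 0.22 over the 18 alternative fits. For change in either direction, fry gave this list an adjusted p of 0.00611, 1 of 16 lists so called, and the list of topology and nucleoid proteins 0.0918. The member of the supercoiling list with the smallest p was fimA (log2 fold change 2.74, SE 0.51). It also belongs to the list of fimbriae and curli, so the 2 lists are not independent.

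In nitrogen limitation genes, glnK fell, the 1 of 25 past the threshold over all genes, while glnP and glnH of glutamine transport had 2.08 (SE 0.41) and 1.89 (SE 0.54) and rutB of pyrimidine breakdown had -2.76 (SE 0.74). Adjusted over the list alone, 1 was higher and 1 lower. The list median was 0.53 and its mean -0.11, opposite in sign, and the camera adjusted p was 0.611. The median turned under some alternatives, to -0.0546 in limma-voom, -0.54 with the share covariate and -1.05 without mutant library 3, where the camera adjusted p was 0.0190.

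Change was grouped along the chromosome. The moving median of log2 fold change over 50 neighbouring genes ranged over 1.93, where a permutation test over 1000 random gene orders gave p = 0.001, the smallest they can give. The highest window, from glpQ to nuoC (lower coordinates of these genes 2349935 and 2402055), had a median of 1.04 with 40 of 50 genes positive. It holds the nuo operon apart from nuoA and nuoB. The lowest window, from ravA to proM (lower coordinates 3929597 and 3982735), had a median of -0.89 with 9 of 50 positive. Genes of one operon are neighbours and share a transcript, and against random orders of blocks of 10 neighbouring genes the range no longer passed (p = 0.0659, permutation test).

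Coding length and change were related. The 364 coding genes of at most 300 nt had a median log2 fold change of -0.57, against 0.06 for longer genes, and 55 genes of at most 150 nt had -1.09. Relative to longer genes, the level of the short genes was 0.30 ± 0.14 (log2, SD, n = 3) in the parent libraries and -0.31 ± 0.29 (SD, n = 3) in the mutant libraries, with no overlap (exact two-sided permutation test p = 0.1, the smallest possible). Of the 7 genes that fell, 4 had coding regions of at most 300 nt.

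**Figure D4:**
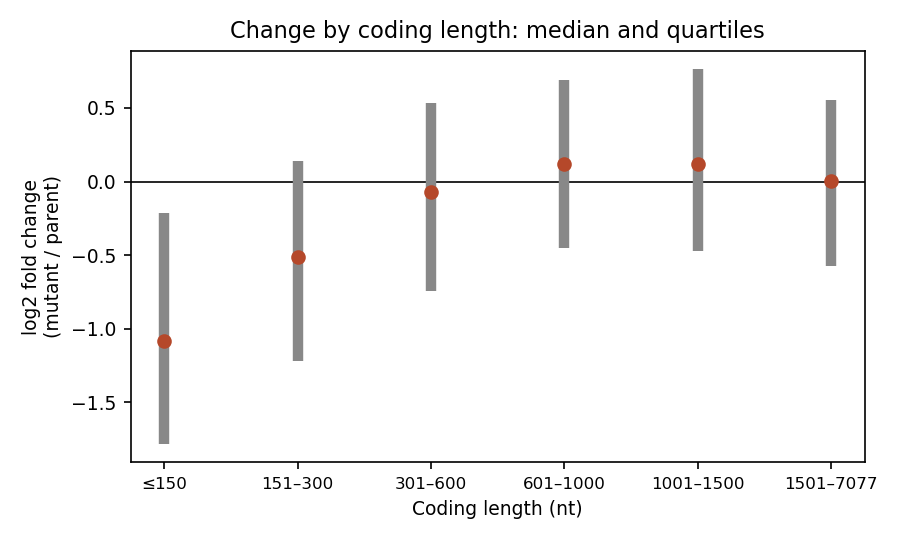
Median (points) and quartiles (bars) over genes of the log2 fold change of mutant over parent, by coding length in nt. The median was -1.09 for genes of at most 150 nt, -0.51 from there to 300 nt and 0.12 for genes of over 600 to 1000 nt.

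The authors' deposited table lists 276 named genes with a q under 0.05, 115 with a higher and 161 with a lower Expression value in the mutant. All 276 had the same direction in the edgeR fit, and 218 of them had an unadjusted p under 0.05 there. In the authors' deposited table hsdM has a p of 1 and a q of 1 and cspI a p of 0 and a q of 1. Of the 10 genes called in edgeR, 1 has a q under 0.05 in the authors' deposited table.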

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

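The tests in this part were chosen after the results were seen, except the count of splits for the change along the chromosome. A signal appeared in the 39 predicted RNAs that have no gene symbol of their own and enter no comparison of the report. Adjusted over those RNAs alone, 6 differed between the groups in edgeR, with adjusted p from 0.00649 to 0.0296. Their unadjusted p ran from 0.000166 to 0.00456 in edgeR. Each was above that of nuoM (0.000109 in edgeR), the largest among the genes called over all genes. The predicted RNA at 2393158 to 2393177, between nuoM and nuoL on the minus strand, had a log2 fold change of 2.61 (SE 0.37), and that at 762893 to 763013, between sucB and sucC on the plus strand, 3.27 (SE 0.60). Between rluE and icd, at 1195054 to 1195087, the value was 3.28 (SE 0.82). Those at 2644391 to 2644432, between rlmN and ndk, and at 3781018 to 3781041, between lldD and trmL, had 2.86 (SE 0.51) and 4.45 (SE 0.84). The 1 that was lower, at 3073694 to 3073789 between epd and yggC, had -3.09 (SE 0.66), and each of the 6 had no overlap between the 3 parent and the 3 mutant libraries. The predicted RNA described as antisense to rnpB did not pass (-3.04, SE 0.90, adjusted p = 0.0569 in edgeR). Among flanking genes named above, nuoM had 3.07, sucB 3.91, sucC 4.14 and icd 3.31, the same direction as the predicted RNAs beside them. Whether the reads of the 6 belong to the transcripts of the flanking genes was not tested.

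With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 10 genes past the threshold in edgeR and the highest of the other splits gave 0, so 1 of 10 splits gave as many. At an unadjusted p under 0.05 the real split had 949 genes and the others 11 to 699, the highest for parent library 1 with mutant libraries 2 and 3 against the rest. For the gene lists the order was the opposite: the real split called 9 lists, the highest other split called 16, and 10 of 10 splits called as many as the real one, which points to a structure of the samples that the preset correlation of camera does not allow for. The range of the moving median along the chromosome was 1.93 in the real split and at most 1.48 in the others, so 1 of 10 was as wide. In DESeq2 the real split called 552 genes and the highest other 170. In voom with library quality weights these were 726 and 669, the latter for parent libraries 1 and 2 with mutant library 3 against the rest, which again points to a structure of the samples beside the groups.

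TCA cycle, respiratory and carbon source genes lay higher in the mutant libraries by the median of each list. The carbon source list overlapped between the groups, with parent library 1 (0.42) above mutant library 1 (0.38) in its median relative level. Reads on rnpB and ssrA cannot produce the TCA cycle difference by distorting the scaling between libraries, since a factor per library moves all genes alike and the TCA cycle median lay 3.20 (log2) above the median of all tested genes. RNA quality or library preparation that goes with the rnpB and ssrA share cannot be told apart from the genotype, because the share separates the groups: with it as a covariate the TCA cycle median was 0.54, against 3.18 without it, that of NADH dehydrogenase and cytochrome oxidases 1.01 against 1.66, and that of secondary carbon source use -0.30 against 1.68. A later growth state of the mutant cultures also stays open: the median RpoS stationary phase level of the mutant libraries minus that of the parent libraries was -0.30, while mutant library 3 stood at 1.63 and mutant library 2 at -0.54, a spread wider than that gap. The list's median log2 fold change was 0.55, opposite in sign to the gap. Ribosomal protein genes stood at 0.20, 0.64 and -1.41 in mutant libraries 1 to 3 and at -0.03, 0.22 and 0.59 in parent libraries 1 to 3. High RpoS and low ribosomal levels thus met only in mutant library 3. Loss of HsdM itself remains among the open explanations and was not separated from these.

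Short coding genes and cold shock genes lay lower in the mutant libraries. Fewer short RNAs recovered in the mutant libraries is a candidate explanation for the short genes as a class, whose level relative to longer genes was lower by -0.61 (log2, mutant minus parent) with no overlap (exact permutation test p = 0.1). That difference is the pattern itself and no test of the explanation. The tRNA share of counts overlapped, at 1.03%, 2.77% and 8.44% in parent libraries 1 to 3 and 5.49%, 1.85% and 0.64% in mutant libraries 1 to 3. The rnpB and ssrA share was lower in the mutant. For the cold shock list, 0% of 10000 random lists matched on coding length had a median as low as -1.73, and their 2.5th percentile was -0.999. The random genes were drawn independently, whereas the members of the cold shock list had an estimated correlation of 0.46, so the random spread may be too narrow. The list was also picked for this comparison after its low median was seen. The comparison thus cannot decide whether lower recovery of short RNAs accounts for the whole of the cold shock list. Chilling of the parent cultures before lysis stays open, because no harvest record was used here. That 5 of the 5 genes cspA, cspB, cspG, cspI and deaD were lower in all mutant libraries largely restates the pattern and is no test of chilling. An effect of the genotype on these genes is likewise untested.

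The genes mcrB and mcrC lay higher in the mutant libraries, short of the threshold over all genes in the main edgeR fit. Of 18 alternative fits, mcrB passed that threshold in 4 and mcrC in 2. Read-through from the altered hsdM locus might also raise hsdS, which lies between hsdM and mcrB on the same strand. The log2 fold change of mcrB exceeded that of hsdS by 2.81 (SE 0.49, taken as if the genes varied independently). That difference cannot decide on read-through, since hsdS overlaps hsdM and its own transcription may have changed with the locus. RNA quality or library preparation that goes with the rnpB and ssrA share cannot be told apart from the genotype here either, since the share separates the groups: with the share as a covariate the value for mcrB was 1.47, against 2.25 without it. A biological response to the loss of HsdM is a hypothesis that stays open.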

How the results depend on the processing

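Tests added after the data were seen were upper-quartile factors, quality weights, the rnpB and ssrA share as a covariate, the paired removal of parent library 1 and mutant library 3, the removal of rnpB and ssrA, block shuffles, and the alternative fits for the chromosome. The log2 fold change of hsdM in mutant against parent held its direction in all 18 alternative fits and its side of the threshold in all but the covariate fit (-8.58, adjusted p = 0.0908 in edgeR, against 1.05e-83 to 0.0293 in the others). The covariate fit leaves 3 residual degrees of freedom and the replicate block, which kept the call, leaves fewer. Why the covariate fit lost the call was not tested. The hsdM value ran from -8.43 to -8.18 when single libraries were left out.

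Counts of called genes (10, with 3 higher and 7 lower) changed with the tool and the libraries, and the cause was not tested. DESeq2 gave 552 (246 higher, 306 lower), limma-voom 17 (9 higher), voom with quality weights 726 (319 higher, 407 lower), the filter at a mean of 50 counts 6 (4 lower), and the covariate fit 0 (0 higher, 0 lower; 78 at an unadjusted p under 0.05). Without parent library 1 and mutant library 3 it was 189 (152 higher, 37 lower), and all 10 genes were among them. Leaving out single libraries gave 1 to 78 genes (0 to 43 higher, 1 to 70 lower), with 60 without parent library 1, 78 without parent library 3 and 1 without any other. RLE factors, upper-quartile factors, no filter, no rRNA and tRNA genes and no rnpB and ssrA gave 7 to 11. With upper-quartile factors the median over genes of the change in log2 fold change was -0.118. The share of higher calls was 30.0% in TMM and 22.2% with upper-quartile factors.

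Equal replicate numbers did not pair the samples: the deviations from the group means of same-numbered libraries correlated, across genes, at -0.616, -0.00955 and -0.491, and no sample correlated best with its own number. With the replicate block the count of called genes was 1 (0 higher, 1 lower, which was hsdM) and lists were 8.

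The list count of 9 was 8 to 15 over the 18 fits: 14 with quality weights, 15 with the covariate, and 9 to 15 without single libraries, the highest without mutant library 3. It was 0 in camera with an estimated correlation, 1 in fry for a shared direction and 16 in fry for change in either direction. With the covariate the medians turned for secondary carbon source use (-0.30) and the hsd locus neighbours (-0.19). Of 180 list values 165 kept their side, 13 were no longer past the threshold and 2 turned. Against random orders of single genes, the range along the chromosome stayed past the threshold in all fits and windows. It ran from 1.23 with the share covariate to 3.98 with windows of 20 genes, and ranges over different window sizes cannot be compared. Such orders separate the genes of an operon, so these fits cannot show that the result holds beyond operons. Shuffled blocks of 10 neighbouring genes were used on the main fit alone, and there the range of 1.93 no longer passed.

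Of 1036 values for 58 named genes, 835 kept direction and side, 59 fell short of the threshold, 119 passed it newly and 23 turned, in 9 genes that had not passed. The log2 fold change of mrr was 0.0168 with RLE factors, 0.0167 in DESeq2, 0.0676 in limma-voom, 0.10 with the replicate block, 0.14 with quality weights and 0.29 without parent library 1 and mutant library 3. The log2 fold change of gyrA was -0.0421 with upper-quartile factors and that of fis 0.35 with quality weights. With the covariate, hsdR had -0.28, symE -0.93, the log2 fold change of gyrB was 0.0752 and the log2 fold change of tnaA was -2.95. Without single libraries the ranges were -0.32 to 0.61 for mrr, -0.16 to 0.47 for symE, -0.0823 to 0.26 for gyrA, -0.47 to 0.18 for topA, -1.14 to 0.71 for fis and -0.23 to 0.0541 for hns.

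limma on the deposited RPKM values was not run, because they hold 1 value per group, and the comparison of genes with EcoKI sites was not run without a genome sequence. Depth limits genes with few reads, such as ynfN. With median counts per gene of 538 to 1875, the biological coefficient of variation of 0.527 bears more on the rest. In simulations without correlation between genes, edgeR recovered 36.4% of 4-fold changes.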

Other observations

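The comparison of tnaA and the reading of single libraries here were chosen after their values were seen. Beyond the lists above, 27 of 36 lists did not pass camera, with adjusted p from 0.0610 to 0.967. Heat shock genes had 15 of 19 positive log2 fold changes and a median of 1.29, and RpoS stationary phase genes 22 of 31 and a median of 0.55. Both turned without mutant library 3 (-0.17 and -0.26), without it and parent library 1 (-0.0129 and -0.14) and with the rnpB and ssrA share as a covariate (-0.32 and -0.53), and the RpoS median also with library quality weights (-0.0495). Glycolysis genes had a median of 0.88 and porin and lipoprotein genes 0.75, and both turned with the rnpB and ssrA share as a covariate (-0.24 and -0.0241). Pyrimidine biosynthesis genes had a median of 0.59 and kept its sign in the 18 alternative fits. Oxidative stress genes went both ways, with 2 higher and 7 lower of 23 when adjusted over the list alone, and phosphate starvation genes had 1 higher and 4 lower of 20. SOS response genes had a median of -0.35 and prophage genes -0.18, with camera adjusted p of 0.205 and 0.611. Ribosomal protein genes had a median of -0.30, with 33 of 54 negative, and it turned to 0.0962 without mutant library 3 and to 0.00515 without parent library 3, and was also above 0 without parent library 1 and mutant library 3 together (0.0852), with library quality weights (0.0975) and with the share as a covariate (0.0523).

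Tryptophanase, tnaA, a gene under catabolite control, overlapped between the groups. It had 652, 9.66 and 3.30 CPM in parent libraries 1 to 3 and 281, 482 and 19273 CPM in mutant libraries 1 to 3 (log2 fold change 4.91, SE 2.44, adjusted p = 0.267 in edgeR). Without parent library 1 the log2 fold change was 10.1, and without mutant library 3 it was 0.78. The TCA cycle list had its highest parent level in the same parent library 1 (-0.16, against -1.85 and -2.56) and its highest mutant level in the same mutant library 3 (2.76, against 0.67 and 1.41).

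In the authors' deposited table, 1046 of 1522 named genes with a p under 0.05 have a q of 1, among them 236 with a p under 1e-10, while 276 genes have a q under 0.05. The median RPKM there is 15 in the parent and 29 in the mutant, and the median Expression value 33 and 29.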
